A study of Mus musculus with 6 samples.

How the data were processed

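Bulk RNA sequencing was done on epithelial cells of the mouse ileum. Per the labels' protocols, the epithelium was stripped with EDTA, dissociated into single cells with TrypLE and sorted by GFP, and both GFP-positive and GFP-negative cells were kept. Total RNA was extracted with a micro kit, cDNA was made with SMART-Seq v4 and libraries with Nextera XT, and the labels describe the libraries as non-directional. Neither step adds molecular identifiers that the sources name, so intervals given for counts cover counting error only. The titles number mice 1, 2 and 3 in each fraction, and samples were grouped by the GFP status in their labels, with 3 libraries per group. The replicates are therefore separate animals.

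Per the submitters' processing notes, the tools were Trim Galore, STAR, featureCounts and DESeq2 and the genome build was GRCm38, and versions are not given in the sources used here. The design text of the series states that genes were counted by featureCounts in unstranded mode with default settings. Both tables deposited by the authors were used. One holds raw read counts per gene symbol, made by the authors, for 54735 genes, of which 23426 had a count in any library, and it has no row for unassigned reads. The other holds normalised values, treated here as a signal in count-like units that the authors deposited for 11827 genes. Each column of it equals the raw counts of the same library divided by 1 constant. After multiplication by that constant 100% of the values were whole to within 0.001 reads and equal to the raw counts, and the constants match DESeq2 size factors computed on the genes kept there. Of the 11817 kept genes with a known biotype 11801 (99.86%) are protein coding. The rule by which the authors kept genes is not stated. No column was left without a sample (0 unmapped).

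Without strand, reads in exons shared by overlapping or antisense genes cannot be told apart, and default featureCounts settings leave them unassigned, which can lower the counts of such genes. Reads of an antisense transcript outside its annotated exons can still be counted for the other gene. Default featureCounts settings can also lower the counts of near-identical copies, so defensin, Reg3, Gal3st2, Gstm and Cyp genes are reported as uncertain. The reads of an introduced Satb2 transgene and of endogenous Satb2 share 1 symbol. GFP reads are not analysed here.

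Gene coordinates were taken from GENCODE M21 on GRCm38, in which 98.85% of the symbols of the raw table were found. The release used by the authors is not given in the sources used here.

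Library totals ran from 10577796 to 14701442 counts. At this depth 12091 genes passed the filterByExpr function of edgeR with its defaults (minimum count 10, minimum total 15) and were tested. Counts were scaled by TMM, with factors from 0.855 to 1.172, and CPM values are TMM-normalised. The main test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit, glmQLFTest, R 4.3.3) with the group as the only term, and Benjamini-Hochberg adjusted p under 0.05 counted as changed. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. Means are given with the SD over 3 libraries. The test was tried on simulated counts with the means and library sizes of these 12091 genes, of which 100 were changed by log2 1 and 100 by log2 2. It recovered 44% and 76% of them, and 6.2% of its calls were false. The simulated counts had no mouse effect and no correlation between genes, and far fewer genes changed than were called in the data. These rates therefore need not hold for the data.

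Before the data were examined, 24 gene lists were fixed for cell types of the ileum and colon, for their functions, for other cell types that the sort could hold and for stress. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with adjustment over the 24 lists. The correlation was also estimated from the data, and the directional test fry was run. Counts of list members use the adjusted p over all genes, and a second count uses p values adjusted over the list alone. Named genes were also chosen by a rule fixed beforehand. It takes Satb2, then the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05, a mean of at least 10 CPM, non-overlapping groups and a name that is not that of a predicted gene. It then takes up to 3 called members of each list with the largest changes, or its 2 most abundant members where none was called. Genes named outside this rule, such as members that moved against their list, were chosen after their values were seen, and their calls were not followed through the alternatives.

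Whether the mouse numbers pair the libraries was checked on 6508 genes with a mean log2 CPM of at least 3. The titles give the same mouse numbers in both fractions, and per the labels' protocols both were collected from the sorted suspensions. Deviations from the group means correlated at 0.26, 0.30 and 0.41 across genes for libraries with the same number, and at 0.01 or below for every other combination. The numbers were therefore taken to pair the libraries, and a fit with the mouse as a block was run beside the main one. The first principal component (53.0% of variance) separated the groups and the second (15.8%) set mouse 3 apart in both. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 16.9 to 26.3), so all were counted.

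Alternatives fixed beforehand were DESeq2 1.42.0 size factors in edgeR, no count filter, a filter of CPM of at least 1 in 3 libraries, the DESeq2 Wald test, limma-voom with quality weights, a robust dispersion prior, the mouse block, and limma on log2 of the deposited normalised values plus 1 for genes with a mean of at least 10. Others were a 2-fold limit, an adjusted p under 0.01, the count without families of near-identical copies, and leaving out each library and each mouse. Chosen after the data were seen were edgeR on the reads recovered from the normalised table, scaling by library size alone, the mouse block with offsets for transcript length and GC content, and leaving out Muc2 before scaling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.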

Results

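RNA was sequenced from epithelial cells of the mouse ileum, the last part of the small intestine, after the cells had been sorted by flow cytometry into GFP-positive and GFP-negative fractions. According to the labels, the GFP-positive cells overexpressed SATB2 and the GFP-negative cells were the controls. SATB2 is a chromatin-binding regulator of transcription, found in the gut mainly in the colon epithelium. Each fraction was collected from mice 1, 2 and 3, which gave 3 libraries per group and 6 in all. The libraries held 12228928, 11574736 and 12021292 counts for the GFP-negative cells of mice 1, 2 and 3. Those of the GFP-positive cells held 12015361, 10577796 and 14701442 counts. The comparison addresses how the transcriptome of ileal epithelial cells with added SATB2 differs from that of GFP-negative cells of the same tissue.

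Satb2 itself was measured first, as a check of the labels. Its normalised expression was 72 ± 15.7 CPM (TMM-normalised, SD, n = 3) in the GFP-negative cells and 2530 ± 553 CPM in the GFP-positive cells, a 35.1-fold difference (log2 fold change 5.14, SE 0.225, edgeR quasi-likelihood adjusted p = 1.17e-06). The raw counts were 1100, 728 and 1048 in the GFP-negative libraries of mice 1, 2 and 3, and 25526, 20268 and 39594 in the GFP-positive libraries. The gene lies on chromosome 1 from 56793981 to 56978650 (GRCm38), and its exons overlap those of the antisense genes 9130024F11Rik and Gm4081. Default featureCounts settings leave reads in such shared parts unassigned, which can lower its count. The counts also do not separate the endogenous gene from an introduced copy.

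In the GFP-positive cells, 12 of 16 tested goblet cell genes and 11 of 13 tested genes of colonic absorptive cells (24 listed) were higher by the edgeR quasi-likelihood test. In the same test 18 of 23 proliferation genes, 10 of 17 enteroendocrine genes and 9 of 14 stem cell genes were lower. Of 12091 genes tested, 2084 (17.2%) changed at an adjusted p under 0.05 (edgeR quasi-likelihood test). Expression was higher in the GFP-positive cells for 1142 of them, 653 by more than 2-fold, and lower for 942, 525 by more than 2-fold. Values of the groups did not overlap for 4391 genes, or 36.3% of those tested, against 10% by chance for 3 libraries against 3. Scaling by library size alone, a choice made after the data were seen, shifted the median log2 fold change of all genes by -0.327. It gave 659 genes higher and 2528 lower (20.7% of calls higher, against 54.8%), so directions are given relative to TMM scaling. DESeq2 size factors gave 1162 higher and 925 lower, and leaving out Muc2 before TMM scaling gave 1140 and 939. The count of changed genes was 328 against a 2-fold limit and 1032 at an adjusted p under 0.01. It was 1380 without the GFP-positive library of mouse 2, 1058 without mouse 1 and 886 without mouse 2.

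Retnlb, which encodes a secreted goblet cell protein (chromosome 16, 48816856 to 48818892), rose from 0.224 ± 0.266 to 26.4 ± 26.4 CPM (n = 3 each), with a log2 fold change of 6.82 (SE 0.943, edgeR adjusted p = 0.000918). The sulfotransferase gene Gal3st2c (chromosome 1, 93990509 to 94017147) rose from 0.4 ± 0.26 to 36.2 ± 4.71 CPM (88.3-fold, log2 fold change 6.46, SE 0.352), although near-identical family members can share its reads. B3galt5, a galactosyltransferase gene (chromosome 16, 96235801 to 96319859), rose from 2.48 ± 0.547 to 128 ± 37.9 CPM (51.4-fold). Car1, a carbonic anhydrase gene (chromosome 3, 14766216 to 14808368), rose from 6.52 ± 7.28 to 296 ± 222 CPM (45.2-fold). Lpo, which encodes lactoperoxidase (chromosome 11, 87806428 to 87828289), rose 43.9-fold, and Il1r1, the interleukin-1 receptor gene (chromosome 1, 40225080 to 40317257), 38.5-fold. B3gnt6, the core 3 O-glycan synthase gene (chromosome 7, 98192417 to 98199481), rose 38-fold, and Reg4, a secreted lectin gene (chromosome 3, 98222156 to 98236748), 36.3-fold. Reg4 was the most abundant of these, at 15 ± 0.721 CPM in GFP-negative and 545 ± 208 CPM in GFP-positive cells (log2 fold change 5.18, SE 0.291, edgeR adjusted p = 2.96e-06). Leaving out 1 library moved several of these folds by over 1.5 times. The log2 fold change of Retnlb (6.82) was 8.26 without the GFP-negative library of mouse 2 and 5.58 without the GFP-positive library of mouse 3. That of Gal3st2c was 7.05 without the GFP-negative library of mouse 1. Without the GFP-negative library of mouse 1, Car1 (5.50) was at 6.99 and Lpo (5.46) at 6.74, and without the GFP-positive library of mouse 1 they were at 4.77 and 4.68. Retnlb lost its call only in limma-voom (adjusted p = 0.0575; 3.83e-67 to 0.0575 over 21 alternatives), and Car1 only with a robust dispersion prior in edgeR (adjusted p = 0.0562; 1.02e-160 to 0.0562).

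Among the falls covered by the naming rule, which needs a mean of at least 10 CPM, the largest was in Sst, which encodes the hormone somatostatin (chromosome 16, 23889573 to 23890958). Sst fell from 160 ± 59.4 to 2.51 ± 2.46 CPM (62.4-fold lower, log2 fold change -5.96, SE 0.626, edgeR adjusted p = 0.000186). Olfm4, a marker of small intestinal stem cells (chromosome 14, 79984081 to 80023139), fell from 63.9 ± 5.15 to 2.80 ± 1.79 CPM (22.2-fold lower), and its exons overlap Gm6999. Myrf, which encodes a membrane-bound transcription factor (chromosome 19, 10208272 to 10240748), fell from 177 ± 50.6 to 9.76 ± 3.37 CPM (18.0-fold lower). The galectin gene Lgals2 (chromosome 15, 78850860 to 78855529), whose exons overlap Cdc42ep1, was 14.8-fold lower, and the Rag GTPase gene Rragd (chromosome 4, 32983037 to 33022180) was 14.5-fold lower. Clic6, an intracellular chloride channel gene (chromosome 16, 92485736 to 92541243) was 9.29-fold lower. Plcb2, a phospholipase C gene (chromosome 2, 118707517 to 118728438), was 8.91-fold lower, and Arx, an enteroendocrine transcription factor gene (chromosome X, 93286445 to 93298357), was 7.62-fold lower. The 8 falls and the 8 rises were chosen among genes whose groups did not overlap. The log2 fold change of Sst was -6.88 without the GFP-positive library of mouse 1, -6.74 in limma-voom and -6.83 on the deposited normalised values. That of Clic6 (-3.22) was -3.90 without the GFP-positive library of mouse 3. That of Plcb2 (-3.16) was -2.39 without the GFP-negative and -4.18 without the GFP-positive library of mouse 1. Plcb2 lost its call without the GFP-negative library of mouse 1 (adjusted p = 0.0672), the GFP-positive library of mouse 2 (0.0816) or mouse 2 (0.152), in limma-voom (0.0624) and with a robust dispersion prior (0.0958). Over its 21 alternatives the adjusted p ran from 8.78e-28 to 0.152. The fits with a library or mouse left out had no mouse block. With all libraries and the mouse as a block, the edgeR adjusted p of Plcb2 was 3.68e-05.

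**Figure D1:**
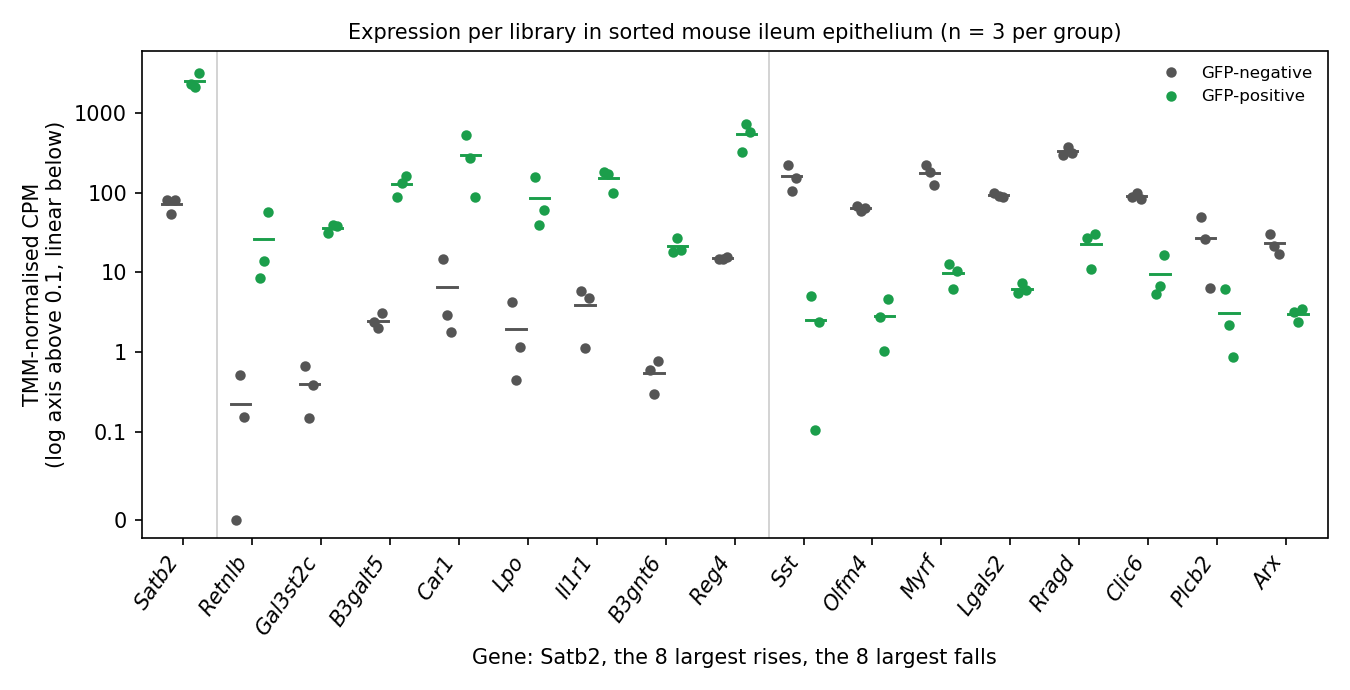
Normalised expression of Satb2, the 8 largest rises and the 8 largest falls in each library, with CPM on an axis that is logarithmic above 0.1 and linear below it. Points are single libraries (3 GFP-negative in grey, 3 GFP-positive in green), and bars are group means. The rises and falls shown were chosen among genes whose groups do not overlap, and Satb2 stands at 72 CPM against 2530 CPM on average.

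Goblet cells make the mucus of the gut. Of 16 goblet cell genes tested, 12 were higher, 2 lower and 2 did not pass (13 higher and 2 lower when adjusted over the list alone), with a median log2 fold change of 1.52. Muc2, which encodes the main secreted mucin of the gut (chromosome 7, 141690340 to 141754693), rose from 25300 ± 5170 to 156000 ± 6490 CPM (6.16-fold, log2 fold change 2.62, SE 0.14, edgeR adjusted p = 2.24e-06) and took 2.84 ± 0.636% of raw counts in GFP-negative and 13.9 ± 1.06% in GFP-positive libraries. Spink4, which encodes a secreted protease inhibitor, rose 6.66-fold (39.7 ± 5.72 to 264 ± 64 CPM), and the kallikrein gene Klk1 rose 5.30-fold (62.2 ± 10.5 to 329 ± 27 CPM). The 2 members that fell, named after their values were seen, were Clca1 (979 ± 439 to 334 ± 152 CPM, log2 fold change -1.55, edgeR adjusted p = 0.0125) and Fcgbp (6650 ± 1220 to 4700 ± 571 CPM, log2 fold change -0.50, edgeR adjusted p = 0.0355), which both encode secreted components of mucus. Of 10 listed genes of colonic secretory cells 7 were tested, of which 5 rose and none fell, the same counts as when adjusted over the list alone. Their median was 1.13, and the largest rises were in Retnlb, Reg4 and Spink4. The camera set test gave an adjusted p of 5.05e-16 for the goblet list and 1.18e-10 for the colonic secretory list with its preset correlation, and neither call held with an estimated correlation (adjusted p = 0.105 and 0.0798). Over 24 alternatives the adjusted p ran from 9.46e-27 to 0.28 for the goblet and from 2.09e-16 to 0.136 for the colonic secretory list.

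Genes typical of absorptive cells of the colon rose in 11 and fell in 2 of the 13 tested members of the list, with the same counts when adjusted over the list alone and a median log2 fold change of 1.78. The list has 24 members, and the rest were not tested. A gene nearly absent from GFP-negative cells, such as Scnn1b, passes the count filter only where GFP-positive cells express it. The tested members are therefore tilted towards rises. Scnn1b, a subunit of the epithelial sodium channel, had 2 counts over the 3 GFP-negative libraries and 378 over the GFP-positive ones, a ratio of 228 (62.8 to 1890, 95% counting interval). Both counts came from the GFP-negative library of mouse 3, without which the GFP-negative count was 0. B3galt5 and Car1 were the next largest rises. The 2 that fell, named after their values were seen, were the carbonic anhydrase gene Car4 (41.7 ± 8.99 to 16.7 ± 2.79 CPM, log2 fold change -1.32, edgeR adjusted p = 0.00167) and the water channel gene Aqp4 (21.4 ± 4.05 to 6.89 ± 2.49 CPM, -1.62, 0.00367). Of 17 tested genes (21 listed) of ion and water transport in the colon, 6 of which are also in another list, 10 rose and 3 fell. The falls were Car4, Aqp4 and the bicarbonate transporter gene Slc4a4, the counts were the same when adjusted over the list alone, and the median was 1.04. The carbonic anhydrase gene Car2 had 2 or 3 counts per GFP-negative library and 23 to 276 per GFP-positive library (log2 fold change 6.20, SE 0.957, edgeR adjusted p = 0.00167), but its call was lost in limma-voom (0.156; 1.61e-36 to 0.156 over 21 alternatives). The chloride channel gene Best2 had 1 to 3 counts per GFP-negative and 31 to 161 per GFP-positive library (log2 fold change 5.64, SE 0.776, edgeR adjusted p = 0.00088). The log2 fold change of Car2 was 5.40 without the GFP-positive library of mouse 1, 5.51 in limma-voom and 5.11 on the deposited normalised values. That of Best2 was 6.29 without the GFP-negative library of mouse 2, 4.76 without the GFP-positive library of mouse 3 and 4.82 on the normalised values. The absorptive list passed camera with the preset correlation (adjusted p = 1.97e-14) and with an estimated one (0.0259), but not with an estimated correlation and the mouse as a block (0.136; 9.67e-25 to 0.136 over 24 alternatives). The ion and water transport list passed with the preset correlation (5.39e-06) and did not with an estimated correlation (adjusted p = 0.0914; 9.16e-12 to 0.136 over its alternatives).

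Of 14 intestinal stem cell genes tested, 9 were lower and none was higher, also when adjusted over the list alone, with a median log2 fold change of -1.18. Beside Olfm4, Smoc2, which encodes a secreted matrix protein, fell from 75.4 ± 5.56 to 21 ± 7.4 CPM (3.57-fold lower), and Ascl2, a stem cell transcription factor gene, fell from 2.44 ± 0.992 to 0.507 ± 0.0796 CPM. Lgr5, the receptor gene that marks stem cells at the crypt base and was named after its value was seen, fell from 125 ± 16.6 to 50.8 ± 19.3 CPM (log2 fold change -1.30, SE 0.246, edgeR adjusted p = 0.00507). Of 23 proliferation genes, 18 were lower and 1 was higher (22 and 1 when adjusted over the list alone), with a median of -1.13. The replication helicase gene Mcm7 was 2.92-fold lower (43.8 ± 6.42 to 15 ± 0.492 CPM), its exons overlapping Ap4m1 and Cops6, and the spindle checkpoint gene Bub1 and the topoisomerase gene Top2a were each 2.75-fold lower. The member that rose, named after its value was seen, was the mitotic kinase gene Plk1 (128 ± 2.08 to 183 ± 5.99 CPM, log2 fold change 0.52, edgeR adjusted p = 0.0128). Camera with the preset correlation gave an adjusted p of 2.04e-07 for the stem cell list and 1.5e-13 for the proliferation list, and neither call held with an estimated correlation (adjusted p = 0.233 and 0.133, with 1.38e-11 to 0.233 and 1.54e-21 to 0.28 over their 24 alternatives). Ascl2, which had 4 to 45 counts per library, lost its call without any 1 of the libraries other than the GFP-negative library of mouse 2 (up to 0.103), without each of the 3 mice and in limma-voom (0.0625). Its adjusted p over 21 alternatives was 0.00837 to 0.136.

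Of 17 enteroendocrine genes tested, 10 were lower and 1 was higher (12 and 1 when adjusted over the list alone), with a median log2 fold change of -1.69. After Sst, the largest falls were in Gip, which encodes gastric inhibitory polypeptide (13 ± 4.08 to 0.198 ± 0.173 CPM, 59.1-fold lower, edgeR adjusted p = 8.09e-05), and in Ghrl, the ghrelin gene (11.4 ± 2.46 to 0.667 ± 0.451 CPM, log2 fold change -4.07, SE 0.434, edgeR adjusted p = 0.000196), whose exons overlap 2 predicted genes. The GFP-positive libraries held only 0, 3 and 4 counts of Gip. Sct, the secretin gene, named after its value was seen, rose from 5.09 ± 1.89 to 20.3 ± 0.831 CPM (3.99-fold, edgeR adjusted p = 0.00108). Genes of tuft cells, the chemosensory cells of the epithelium, had the lowest median of the lists, at -2.59, but 2 of 8 tested members passed (5 when adjusted over the list alone, and 6 with the mouse as a block). These were Pou2f3, the tuft cell master regulator (15.5 ± 14.8 to 2.15 ± 1.86 CPM), and Avil, which encodes advillin (21.8 ± 13.8 to 3.35 ± 2.15 CPM) and overlaps Tsfm. The groups overlapped for Pou2f3 across mice, but it was lower in the GFP-positive library of each mouse (32.3 to 4.29, 10.1 to 1.04 and 4.23 to 1.12 CPM in mice 1, 2 and 3), and with the mouse as a block its edgeR adjusted p was 0.000354. Camera with the preset correlation gave an adjusted p of 2.58e-11 for the enteroendocrine and 0.0151 for the tuft cell list, and neither call held with an estimated correlation (adjusted p = 0.105 and 0.715, with 3.36e-19 to 0.136 and 1.9e-07 to 0.715 over their 24 alternatives). Without the GFP-negative library of mouse 1, the tuft cell list had an adjusted p of 0.0615 and Pou2f3 one of 0.127. The list also lost its call with DESeq2 (0.0847), fry (0.222) and library size alone (0.118). Without the GFP-positive library of mouse 1 the log2 fold changes were -4.77 for Ghrl, -3.83 for Pou2f3 (-2.85) and -3.31 for Avil (-2.71), and Pou2f3 was at -1.72 without the GFP-negative library of mouse 1. Pou2f3 also lost its call without the GFP-positive library of mouse 2 (0.111) or mouse 3 (0.0834) and without mouse 2 (0.147), in limma-voom (0.0952) and with a robust prior (0.099), with 1.56e-16 to 0.147 over 21 alternatives. Avil lost its call without the GFP-positive library of mouse 2 (0.0573) or mouse 2 (0.129), with 1.45e-19 to 0.129 over its alternatives. With all libraries and the mouse as a block its edgeR adjusted p was 7.54e-05.

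Of 15 nutrient transporter genes, 3 were lower and none was higher, also when adjusted over the list alone, with a median log2 fold change of -0.40. With the mouse as a block 5 were lower and 2 higher. Slc6a20a, an amino acid transporter gene whose exons overlap Ccr9, was 5.8-fold lower (136 ± 21.9 to 23.3 ± 9.39 CPM). Slc7a8, another amino acid transporter gene, was 3.59-fold lower (1010 ± 321 to 280 ± 175 CPM), and the sulfate transporter gene Slc13a1 was 2.47-fold lower. The camera call of this list (adjusted p = 0.0255) was lost with an estimated correlation (adjusted p = 0.715), without the GFP-negative library of mouse 3 (0.127), the GFP-positive library of mouse 1 (0.0819) or mouse 1 (0.064), with fry (0.188) and on the normalised values (0.0515). Its adjusted p over 24 alternatives was 0.00155 to 0.715. The 4 further lists of this kind did not pass camera. Of 16 brush border digestive enzyme genes 2 fell, the sucrase-isomaltase gene Sis (6.02-fold lower, 344 ± 52.6 to 56.9 ± 28.4 CPM) and the maltase gene Mgam (1.87-fold lower), and 1 rose, the meprin gene Mep1a (2.55-fold, 682 ± 298 to 1740 ± 259 CPM). The counts were the same when adjusted over the list alone (5 lower and 2 higher with the mouse as a block, camera adjusted p = 0.284). Of 16 genes of lipid absorption 4 fell and 1 rose (5 and 1 when adjusted over the list alone, camera adjusted p = 0.12). They included Mttp, needed for chylomicron assembly (2.86-fold lower, 125 ± 16.4 to 43.7 ± 14.1 CPM), whose exons overlap Trmt10a. Also among them were the cholesterol transporter gene Npc1l1 (2.36-fold lower, 341 ± 42.9 to 144 ± 34.9 CPM), and the lipoprotein receptor gene Scarb1 (3.60-fold higher). Of 8 genes of bile acid and cobalamin uptake in the ileum, Fabp6, the ileal bile acid binding protein gene, fell (2.58-fold lower, 49.2 ± 8.24 to 19 ± 1.39 CPM) and the bile acid exporter gene Slc51b, overlapping Rasl12, rose (1.62-fold higher), with 2 lower and 1 higher when adjusted over the list alone and 3 lower and 1 higher with the mouse as a block (camera adjusted p = 0.356). Of 22 cholesterol synthesis genes only Dhcr24, the gene of a late enzyme of the pathway, changed (1.56-fold lower), also when adjusted over the list alone (2 lower with the mouse as a block, camera adjusted p = 0.585). Several of these calls were lost with a library or a mouse left out, which also leaves fewer samples in the fit. With all libraries and the mouse as a block, Slc13a1, Dhcr24, Scarb1, Slc51b, Mep1a and Slc7a8 passed (edgeR adjusted p = 3.46e-05 for Slc7a8 to 0.0395 for Slc51b). Slc13a1 lost its call without the GFP-positive library of mouse 2 (adjusted p = 0.0533) and without mouse 3 (0.0962), with 2.37e-06 to 0.0962 over 21 alternatives. Dhcr24 lost it without the GFP-negative library of mouse 1 (0.06), without mouse 1 (0.0961) and without mouse 2 (0.0646), with 0.00106 to 0.0961 over its alternatives. Scarb1 lost its call without the libraries of mouse 2 or 3 in either fraction (0.0525 to 0.0769 each, 0.00119 to 0.171 over its alternatives). Slc51b lost it without the GFP-negative library of mouse 1 or 2 or the GFP-positive library of mouse 2 or 3 (up to 0.133) and with library size alone (0.197), with 0.0216 to 0.277 over its alternatives. The log2 fold change of Scarb1 (1.85) was 2.47 without the GFP-negative library of mouse 1, and that of Slc7a8 (-1.85) was -2.48 without the GFP-positive library of mouse 3. Mep1a and Slc7a8 lost their calls without mouse 1 (0.0617 and 0.067) and with a robust prior (0.0549 and 0.0636), with lowest values of 2.28e-20 and 1.39e-33.

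Paneth cell and antimicrobial genes moved both ways. Of 16 Paneth cell genes 3 fell and 2 rose (9 and 2 when adjusted over the list alone, 8 and 2 with the mouse as a block), with a median log2 fold change of -1.19 and a camera adjusted p of 0.245. The stress-response gene Nupr1 rose 11.8-fold (2.12 ± 0.265 to 25.2 ± 6.96 CPM). Mptx2, a pentraxin gene, was 4.71-fold lower and the defensin gene Defa20 3.43-fold lower, although defensin genes are near-identical copies that can share reads. The GFP-positive libraries of mice 1, 2 and 3 held only 10, 7 and 51 counts of Mptx2 and 9, 11 and 9 of Defa20. Of 9 antimicrobial and villus tip genes 3 fell and 2 rose (4 and 3 when adjusted over the list alone, camera adjusted p = 0.396). The lectin genes Reg3a (15.1-fold lower, with 0, 3 and 4 counts in the GFP-positive libraries) and Reg3g (2.72-fold lower, 592 ± 300 to 218 ± 105 CPM) are paralogs that can share reads, and the transcription factor gene Klf4 was 1.97-fold higher. Mptx2 lost its call without the GFP-negative library of mouse 2 or the GFP-positive library of mouse 1 or 2 (up to 0.0684; 1.09e-07 to 0.163 over 21 alternatives). Its log2 fold change (-2.24) was -3.47 without the GFP-positive library of mouse 3, and that of Reg3a (-3.92) was -3.27 without mouse 2. Reg3g lost its call without the GFP-negative library of mouse 3 or the GFP-positive library of mouse 1 or 2 (up to 0.0991), with DESeq2 (0.0635) and with a robust prior (0.112; 1.63e-19 to 0.112). Klf4 lost it without the GFP-negative library of mouse 2 or 3 or the GFP-positive library of mouse 1 or 2 (up to 0.0867) and with library size alone (0.0865; 0.00147 to 0.186). Defa20 lost it without any 1 of the libraries other than the GFP-negative library of mouse 3 (up to 0.141; 0.0116 to 0.161). With all libraries and the mouse as a block, Mptx2, Reg3g, Klf4 and Defa20 passed (edgeR adjusted p = 4.87e-05 for Reg3g to 0.0322 for Defa20).

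Regional transcription factor genes and genes of xenobiotic metabolism also moved both ways. Of 19 transcription factor genes 3 rose and 3 fell, also when adjusted over the list alone, with a median log2 fold change of 0.06 and a camera adjusted p of 0.892. The forkhead gene Foxa1 rose 3.02-fold (55.6 ± 11 to 168 ± 7.04 CPM, edgeR adjusted p = 0.000173), Foxa3 was 2.09-fold higher, and Hnf4g, a nuclear receptor of enterocytes, was 2.94-fold lower (431 ± 65.9 to 146 ± 38.5 CPM, edgeR adjusted p = 0.000626). Of 18 genes of xenobiotic and retinoid metabolism 4 rose and 5 fell (6 and 5 when adjusted over the list alone, camera adjusted p = 0.712). Their median log2 fold change was 0.16, their mean -0.01. The largest changes were in the cytochrome P450 genes Cyp2d26 (8.63-fold higher) and Cyp3a11 (7.37-fold lower), both from families with shared reads, and in the retinol binding protein gene Rbp2 (4.45-fold lower). These folds rest on few counts. The GFP-negative libraries of mice 1, 2 and 3 held 39, 6 and 14 of Cyp2d26. Those of GFP-positive cells held 0, 2 and 6 of Cyp3a11 and 9, 5 and 15 of Rbp2. The log2 fold change of Cyp2d26 (3.11) was 4.06 without the GFP-negative library of mouse 1, and that of Cyp3a11 (-2.88) was -4.06 without the GFP-positive library of mouse 3. Foxa3 lost its call without any 1 of the libraries other than the GFP-negative library of mouse 1 (up to 0.0786) and with library size alone (0.069; 0.000101 to 0.125 over 21 alternatives). Cyp3a11 lost it without any 1 of the libraries other than the GFP-positive library of mouse 3 (up to 0.128; 0.0108 to 0.202). Rbp2 lost it without mouse 1 (0.0791) or mouse 2 (0.0773; 0.000812 to 0.0791).

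None of 16 lymphocyte genes passed, also when adjusted over the list alone (camera adjusted p = 0.313), and the most abundant were Itgae, an integrin gene, and Rac2, a GTPase gene. Itgae stood at 17.1 ± 5.35 and 20.5 ± 5.07 CPM and Rac2 at 5.64 ± 2.88 and 4.67 ± 0.957 CPM in GFP-negative and GFP-positive cells. Of 8 myeloid genes the complement gene C1qa rose, from 0.496 ± 0.467 to 5.10 ± 2.03 CPM (log2 fold change 3.32, SE 0.635, edgeR adjusted p = 0.00531; 0.0598 without mouse 1, 8.9e-08 to 0.0598 over 21 alternatives), and the list did not pass, with the same count when adjusted over the list alone (camera adjusted p = 0.585). Without the GFP-negative library of mouse 2 the log2 fold change of C1qa was 4.43. Of 5 tested genes of stroma and endothelium (16 listed) only Tagln, which encodes a smooth muscle protein and overlaps Pcsk7, was called, at 0.348 ± 0.109 and 1.43 ± 0.237 CPM (edgeR adjusted p = 0.0434), and with the mouse as a block it did not pass (0.0701). Tagln also lost its call without any 1 of the 6 libraries (0.0985 to 0.159), and over its 21 alternatives its adjusted p ran from 0.0379 to 0.216. The stroma list had a camera adjusted p of 0.988 and the same count when adjusted over the list alone (0 with the mouse as a block). Its median log2 fold change (-0.31) and mean (0.07) differed in sign. Early response genes, which cell dissociation induces, rose in 4 of 17 cases and fell in none (6 and 0 when adjusted over the list alone), with a median log2 fold change of 0.58. Nr4a1, a nuclear receptor gene, was 5.18-fold higher (1.53 ± 0.576 to 7.95 ± 1.5 CPM), the phosphatase gene Dusp1, overlapping Ergic1, 2.91-fold higher (19.5 ± 9.96 to 56.7 ± 1.7 CPM) and Btg2, an antiproliferative gene, 2.28-fold higher. The camera call of this list (adjusted p = 0.0079) was lost with an estimated correlation (adjusted p = 0.251; 0.000587 to 0.28 over 24 alternatives). Btg2 lost its call without the GFP-negative library of mouse 2 or 3 or the GFP-positive library of mouse 1 or 2 (up to 0.121) and with library size alone (0.0812; 2.48e-05 to 0.27 over 21 alternatives). None of 7 mitochondrial genes passed, also when adjusted over the list alone (1 higher with the mouse as a block, camera adjusted p = 0.82). The most abundant, both for subunits of respiratory complex I, were mt-Nd5, which overlaps mt-Nd6, at 384 ± 70.2 and 368 ± 95.1 CPM, and mt-Nd2 at 327 ± 46.5 and 330 ± 82.7 CPM in GFP-negative and GFP-positive cells. Of 10 interferon response genes 2 rose (4 when adjusted over the list alone and with the mouse as a block, camera adjusted p = 0.122). They were Ifit2, 4.32-fold higher, and the GTPase gene Gbp2, 2.76-fold higher. Ifit2 lost its call without mouse 2 (0.0713; 2.93e-08 to 0.0713 over 21 alternatives). Gbp2 lost it without mouse 1 (0.0905), mouse 2 (0.0638) or mouse 3 (0.0572; 0.00118 to 0.0905). Of 8 MHC class II genes H2-DMb1, which serves peptide loading, was 1.93-fold higher (2 higher when adjusted over the list alone and with the mouse as a block, camera adjusted p = 0.585). It lost its call without any 1 of the libraries other than the GFP-positive library of mouse 3 (up to 0.144) and with library size alone (0.141; 0.0157 to 0.257 over its alternatives).

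**Figure D2:**
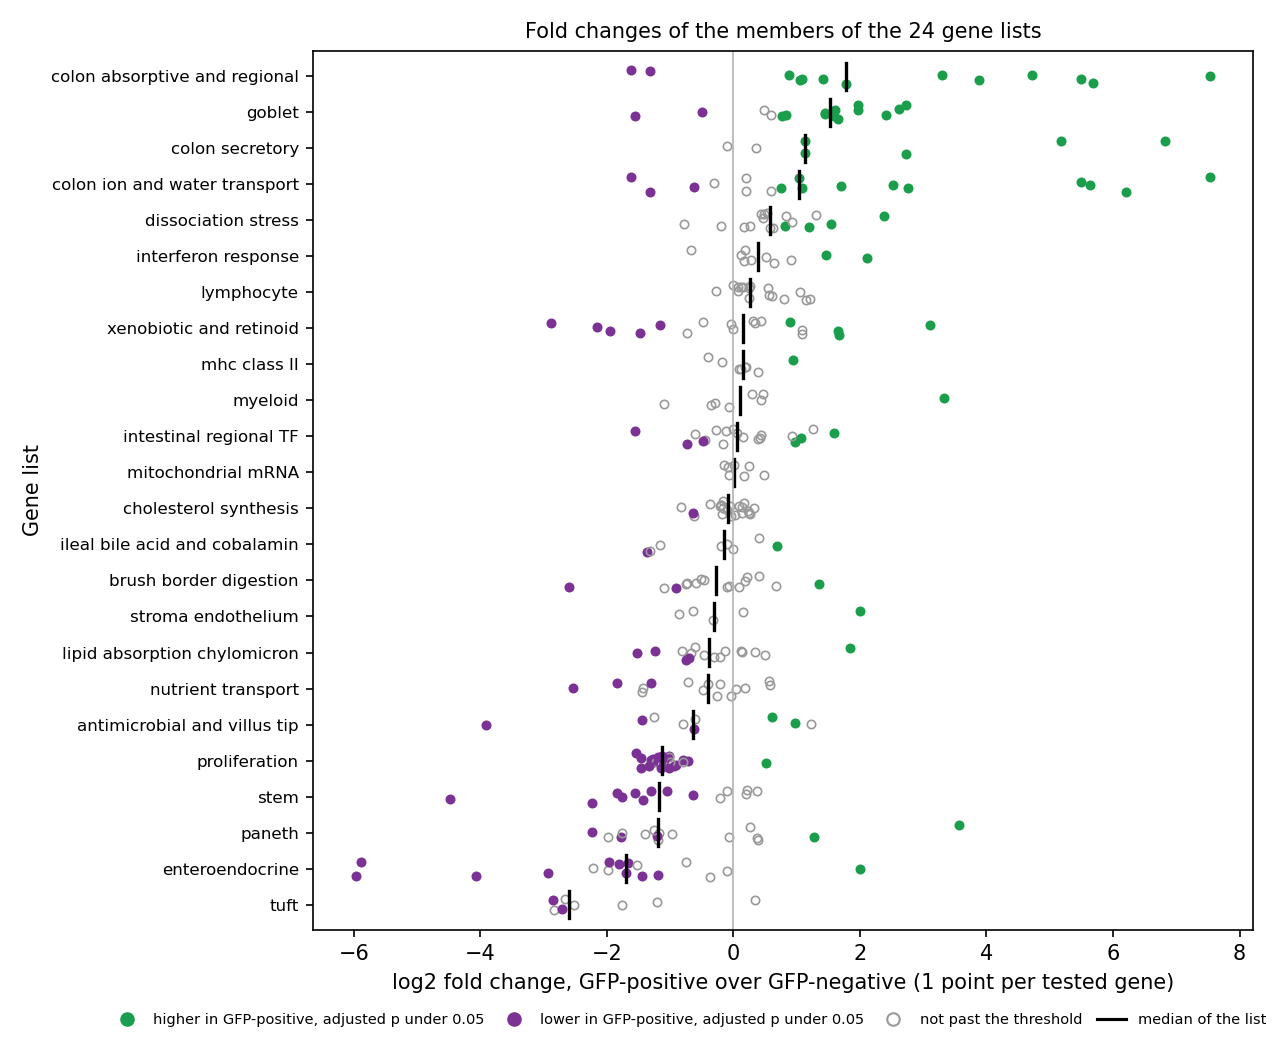
Log2 fold changes (GFP-positive over GFP-negative, TMM scaling) of each tested member of the 24 gene lists, 1 point per gene, with filled points for adjusted p under 0.05 and black bars for list medians. The colon absorptive list has the highest median (1.78) and the tuft cell list the lowest (-2.59), and scaling by library size alone moves all genes by -0.327.

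By the camera test with its preset correlation, 10 of the 24 lists changed, and with an estimated correlation 1 of them, the absorptive colon list, passed. Camera then uses only the residual degrees of freedom of the fit, which are few here. The correlation estimated for the absorptive colon list was -0.02, against 0.02 to 0.80 for the other called lists. Only 13 of its 24 members were tested, with the tilt towards rises given above. The directional test fry, which does not compare members with other genes, called 8 of the 10, all but the tuft cell and nutrient transporter lists. With the same 6 libraries grouped in other ways, the preset test called up to 6 lists where the grouping parted all 3 mouse pairs and up to 11 where it parted 1 pair. Each of these groupings mixed both fractions in unequal numbers on each side and so kept part of the difference between them. Their calls therefore do not show what the test gives without a change. The preset p values alone were still taken as weak evidence, since 9 calls were lost with an estimated correlation.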

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

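Scaling by library size alone, edgeR on recovered reads, the mouse block with length and GC offsets, and leaving out Muc2 were chosen after the data were seen. Satb2 stayed higher and past the threshold under each of its 21 alternatives, with a log2 fold change of 4.81 to 5.29. The count of 2084 changed genes (1142 higher, 942 lower) was 328 (214 and 114) against a 2-fold limit and 1032 (626 and 406) at an adjusted p under 0.01, both stricter by construction. It was 3187 (659 and 2528) with library size alone, which calls 1601 of the 2084 and moves all genes by -0.327. It was 2087 (1162 and 925) with DESeq2 size factors and 2079 (1140 and 939) with Muc2 left out before scaling. Leaving out a library or a mouse gave 886 to 1760 changed genes, 541 to 1034 higher and 345 to 807 lower, with fewer samples in each fit and no mouse block. The count was 1380 without the GFP-positive library of mouse 2, 1058 without mouse 1 and 886 without mouse 2, and the count of lower genes was 570 without the GFP-positive and 589 without the GFP-negative library of mouse 2. The replicate block gave 2586 changed genes (1397 higher, 1189 lower), 2049 of them among the 2084, and the same number of lists, and among the named genes and the 24 lists fixed beforehand it ended the call of Tagln and changed no other call, though it raised the counts of called members in several lists. DESeq2 called 2489 genes, limma-voom 2146 and the fit on recovered reads 2052 (1987 of them among the 2084).

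Of the 10 lists called, 8 passed fry, 1 passed camera with an estimated correlation and 0 did with an estimated correlation and the replicate block. In the last of these the 10 calls had a lowest camera adjusted p of 0.136. Camera with an estimated correlation rests on the residual degrees of freedom of the fit, which so few libraries leave low and the block lowers further. Passing was therefore hard by design, and the lost calls do not show that the members did not change. How much of the loss this accounts for was not tested. Of 63 called named genes besides Satb2, 26 lost their call under some alternative, 17 of them with 1 library left out, 23 with 1 mouse left out and 15 under another alternative, and none of the 63 and none of the 10 lists changed direction. Uncalled lists passed under some alternative in 4 cases (lipid absorption, interferon response, Paneth cell and brush border).

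Direction changed only for results that were not past the threshold, and the cause was not tested. The log2 fold change of mt-Nd2 was -0.01 with limma-voom and with the replicate block, -0.05 with the block and length and GC offsets, -0.31 with library size alone and -0.2 to 0.16 with samples left out. Itgae was at -0.07 with library size alone. With samples left out, mt-Nd5 ran from -0.26 to 0.11 and Rac2 from -0.59 to 0.16. The stroma list turned with no filter (adjusted p = 0.686), DESeq2 (0.975), the normalised values (0.924), fry (0.894), library size alone (0.656) and in some omissions (0.826 to 0.994 over all). The transcription factor list turned with limma-voom (0.992), library size alone (0.91) and in omissions (0.721 to 0.946 over all), the xenobiotic list with no filter (0.918) and in an omission (0.436 to 0.979 over all), and the mitochondrial list in an omission (0.299 to 0.979 over all). Depth limits genes such as Scnn1b, Best2, Car2, Gip, Ascl2, Cyp3a11, Rbp2 and Defa20, which had few counts in 1 group.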

Other observations

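The lists of mucin glycan, fatty acid and sodium uptake genes below, and each test of an explanation, were chosen after the values had been seen, and their criteria in part revised after the tests had been run, except the counts over other groupings of the libraries.

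A list of genes that build and sulfate mucin-type O-glycans was drawn up after the rises of Gal3st2c, B3galt5 and B3gnt6, which it holds, had been seen. Of 62 listed, 47 were tested. Of these, 29 were higher in GFP-positive cells, 1, B4galnt1, was lower and 17 did not pass, with a median log2 fold change of 1.21. Gal3st2c had 9, 2 and 5 counts in the GFP-negative libraries and passed the count filter only through GFP-positive cells. The tested members are therefore tilted towards rises. Papss2, which makes the sulfate donor, rose from 105 ± 21.3 to 1210 ± 112 CPM (n = 3, log2 fold change 3.53, edgeR adjusted p = 1.96e-06), Gcnt3, a core 2 and core 4 branching enzyme gene, from 54.9 ± 8.04 to 320 ± 20.4 CPM (2.54, 4.27e-06), and the fucosyltransferase gene Fut2 from 1.92 ± 1.75 to 45 ± 8.49 CPM (4.55, 0.000183). The hypothesis that these genes rise as a group had a camera adjusted p over the 3 added lists of 1.5e-24 with the preset and 0.0166 with an estimated correlation. It was found and tested on the same libraries, and the tilt of the tested members also favours it.

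Of 24 listed sodium uptake and mineralocorticoid response genes 21 were tested, again with a tilt towards rises through Scnn1b. Higher values were found for 11 and lower for none, with a median log2 fold change of 0.72. They included Nr3c2, the mineralocorticoid receptor gene (241 ± 11.8 to 1070 ± 35.5 CPM, log2 fold change 2.15, edgeR adjusted p = 2.24e-06), and Hsd11b2, which inactivates glucocorticoids (10.9 ± 0.797 to 94.2 ± 11.3 CPM, 3.11, 2.24e-06). As a group they passed camera with the preset (adjusted p = 4.88e-10) but not with an estimated correlation (adjusted p = 0.0514), so the hypothesis of a joint rise was left undecided. Hmgcs2, the rate-limiting enzyme gene of ketone body synthesis, rose from 50.7 ± 11.4 to 1340 ± 272 CPM (log2 fold change 4.72, edgeR adjusted p = 1.57e-06). Of 29 tested genes (35 listed) of fatty acid oxidation and ketogenesis, 5 were higher and 3 lower, with a median of 0.04. Their camera adjusted p was 0.0854 with the preset correlation, 0.0434 with it and the mouse as a block, and 0.232 with an estimated correlation, so the hypothesis of a joint rise was left undecided here too.

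In GFP-positive cells 12 of 16 goblet genes, Muc2 among them, were higher, and the list call was lost with an estimated correlation (adjusted p = 0.105). A larger share of goblet cells with unchanged expression per cell would raise goblet genes, but 2 members at over 100 CPM, Clca1 and Fcgbp, fell. This argues against a larger share of goblet cells of the same kind as the whole cause, but not against a different mix of goblet subtypes. The spread of the log2 fold changes of the 16 members (SD 1.13, median SE 0.204) does not bear on it, since members that other cells also express would rise less. For Muc2, scaling between libraries as the whole cause is argued against, since its log2 fold change was still 2.29 with library size alone. This check covered Muc2 only, not the list. A changed programme within goblet cells or a different mix of their subtypes, alone or with a changed share, may remain as hypotheses, and bulk libraries do not separate them.

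In GFP-positive cells 9 of 14 stem and 10 of 17 enteroendocrine genes were lower and the enteroendocrine gene Sct was higher, and both list calls were lost with an estimated correlation (adjusted p = 0.233 and 0.105). The log2 fold changes had an SD of 1.29 among 14 stem genes (median SE 0.216), with Olfm4 at -4.47 and Lgr5 at -1.30, and of 1.96 among 17 enteroendocrine genes (median SE 0.409). Members that other cells also express would fall less, so this spread does not exclude smaller shares of these cells, and smaller shares, a different mix of enteroendocrine subtypes and changes within cells all stay open. Length and GC offsets found little trend to correct, moving the log2 fold changes of all genes by an SD of only 0.0257. With these offsets and the mouse block, 100% of the 19 called members stayed called. Offsets this small could hardly have ended a call, so this result could not decide whether length or GC caused the falls. The offsets show only that the fitted trend with length and GC across genes was small. Across the tested genes, 99.76% of which had both values, the log2 fold change had a Spearman correlation of 0.015 with length and -0.027 with GC, and genes are not independent replicates.

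GFP-negative libraries held Satb2 counts, at 2.84% of the GFP-positive level overall and 3.5%, 2.56% and 2.55% in mice 1, 2 and 3. If GFP-positive cells carried into the GFP-negative sort were the only source, no other gene should lie below that share. Of 1067 genes higher in GFP-positive cells with at least 5 expected counts, 10 were below it in every mouse, 7 of them with an unadjusted p under 0.05 and 0 with an adjusted p under 0.05 (negative binomial lower tail). Among the 7 were Gm13986 (33 counts against 90.8 expected, adjusted p = 0.0559), Gal3st2c (16 against 41.2, 0.0708), Scnn1b (2 against 12.7, 0.427) and B3galt5 (99 against 146, adjusted p = 1). The adjustment covers many genes with far higher ratios, so the 0 does not decide, and carryover, Satb2 expression in GFP-negative cells and cells with little GFP all stay open.

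The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. Every other split mixes both fractions in unequal numbers on each side. It therefore keeps part of the difference between them and adds the rest to the spread within each side. Neither its gene calls nor its list calls show what would be called without a difference. The real split called 2084 genes in edgeR and the highest other 0, with 3736 and at most 463 genes at an unadjusted p under 0.05. For gene lists the real split called 10 and the highest other 11 by camera with the preset correlation, with 3 of the 10 splits, the real one included, calling as many, and the lowest adjusted p was 5.05e-16 and 1.31e-14. Of the other splits, 3 also part the libraries of all 3 mice, and they called at most 6 lists and 201 genes at an unadjusted p under 0.05. The rest part 1 mouse and keep both libraries of the other mice together, and they call more lists. With an estimated correlation the real split called 1 list and the highest other 1.

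Some shares of raw counts have no explanation here. Lars2 held 7.87 ± 0.446% in GFP-negative and 8.54 ± 0.139% in GFP-positive libraries (n = 3), and Gm26917 3.26 ± 0.476% and 1.59 ± 0.191%. The 85 ribosomal protein genes together held 0.139 ± 0.00146% and 0.0848 ± 0.00356%. Protein-coding genes whose longest transcript is under 1000 nucleotides held 0.779 ± 0.0174% and 0.789 ± 0.00884%, and those of 1000 to 2000 nucleotides 7.04 ± 0.284% and 6.11 ± 0.064%. Those of 2000 to 4000 nucleotides held 41.8 ± 0.381% and 50 ± 0.081%, and longer ones 41.2 ± 0.778% and 36 ± 0.367%. Muc2, placed in the class of 2000 to 4000 by an annotated length of 2926, alone held 2.84 ± 0.636% and 13.9 ± 1.06%. Lengths of single genes are also those of the longest annotated transcript, which need not be the form expressed, so contrasts of length between genes are uncertain. Fabp1, an abundant enterocyte transcript with an annotated length of 553 nucleotides, had 2 to 24 counts per library, while Gapdh (longest annotated transcript 3289 nucleotides) had 53007 to 87224. Malat1 (6983 nucleotides) had 130 to 204, Eef1a1 (1794) 431 to 700 and Lypd8 (1219) 46830 to 115448.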
